A study of Mus musculus with 7 samples.

How the data were processed

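Mature miRNAs were measured by real-time PCR in wound edge tissue of C57Bl6 mice, taken 3 days after wounding from 4 non-ischemic and 3 ischemic wounds. Per the labels, total RNA was isolated with the miRVana kit, 500 ng was reverse transcribed with a pool of looped primers, and PCR was run on an Applied Biosystems 7900HT instrument in plates of 384 wells. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the samples came from separate animals, so the p-values measure only the spread between these samples, which may be partly technical. The software that set the threshold cycle is not given in the sources used here.

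The authors deposited the values in 4 forms. The first holds the raw threshold cycle (Ct) of 316 assays, where a lower Ct means more product and 40 stands where no product was seen. The second, per the file headers a delta Ct, was found to equal the Ct of 5S rRNA minus the Ct of the assay in every sample for 315 of the 316 assays, within 0.0001 cycles. These deposited log2 values were thus made by the authors by subtracting the Ct of each assay from that of 5S rRNA, so that a higher value is a higher level, on a log2 scale if each cycle doubles the product. The exception was 18S, which has the opposite sign, and its level was taken from the raw Ct. The third holds the linear ratio to 5S rRNA, 2 to the power of that delta Ct, as deposited by the authors. The fourth, the authors' deposited table of group means, holds the arithmetic mean of that ratio per group and the fold of ischemic over non-ischemic. The design fixed before the data were examined took the negative of the deposited delta Ct, on the assumption that the sign was the usual one. Since the deposited sign already runs upward with level, the values were used without turning them. The raw table also held 7 columns that repeat the 5S rRNA Ct, and these were not used. Raw Ct columns carry sample numbers, and the same Ct values per sample reappear, with 5S rRNA subtracted, under the titled columns of the delta Ct table.

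Assay names are those of the plate. Here a miRNA is named by the assay name without its species prefix and leading zeros. Of the 316 assays, 306 were miRNAs, 9 were control RNAs and 1 was a fly miRNA assay, which had a Ct above 35 in every sample and was left out. A Ct below 35 was taken as detection. A PCR level has no count of molecules behind it in these data, so precision is given by the spread between samples only, and levels with a Ct near 35 or above are the least precise.

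Ischemic and non-ischemic samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on the log2 levels of the 103 miRNAs with a Ct below 35 in at least 3 samples. Values at Ct 40 were kept as deposited. Differences are ischemic minus non-ischemic on the log2 scale. Single quantities were compared by exact permutation tests of the difference in means, two-sided over all 35 splits, so that the smallest p is 0.0286. Detection per assay was compared by Fisher's exact test. The 24 miRNA lists were fixed before the data were examined and matched on the mature name without its arm, leaving out forms marked with a star. Passenger forms named by their arm were therefore kept, such as miR-30a-3p in the miR-30 family. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, which asks whether members move one way on balance without comparing them with other miRNAs. The lists rest on textbook knowledge, share members with each other, and their members are also expressed by other cells of skin.

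The rule for named miRNAs, also fixed beforehand, took miR-210, the control assays, the 12 largest rises and falls past the threshold, the 12 with the smallest p where fewer than 10 pass, up to 4 members of each list by smallest p, and up to 5 miRNAs detected in 1 group only. It gave 60 miRNAs besides miR-210, of which 39 are named in the text as part of the comparison; that selection was made after their values were seen. Others that are named are said to be chosen after their values were seen. The alternatives tried were global mean, global median, quantile and snoRNA normalization and raw Ct without normalization, other filters and treatments of late Ct, another variance model, an unmoderated two-sample test per assay, linear values, each sample left out in turn, and the replicate number as a block. Small RNA normalization used the mean of the snoRNA assays with a Ct below 35 in all 7 samples.

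The procedure was tested on simulated data with the means and spreads of the 103 miRNAs, 20 of them shifted, in 100 runs of the ischemic against non-ischemic comparison. Shifts of 1, 2 and 3 log2 units were called in 17.4%, 63.3% and 87.5% of cases, with 5.13% of calls false. A list shifted by 2 log2 units was called by camera in 100% of runs. The simulated values were drawn independently for each miRNA, with 1 spread for both groups and no sample set apart from the rest. In the data the estimated correlation within lists ran from -0.14 for lymphocyte to 0.94 for leukocyte miRNAs. The simulation therefore does not show how camera behaves on lists with correlated members. Nor does it show how often shifts are called, or calls are false, where 1 ischemic sample stands apart, as ischemic sample 3 does here. For neighbouring genes, mouse miRNA genes of the GRCm38.p6 annotation were matched by name to 89 of the 103 miRNAs. No genome build is named with the PCR data, so no coordinates are given.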

Results

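The series addressed the effect of ischemia on miRNAs of the wound edge. Ischemic wounds lay within a bipedicle flap, a strip of skin left attached at its ends only so that blood supply to its middle is restricted, and were compared with non-ischemic wounds of the same strain. All samples were taken on day 3, with 4 non-ischemic and 3 ischemic samples. Each sample was measured once for 306 mature miRNAs and 9 control RNAs. A Ct below 35 was reached by 103, 94, 97 and 101 miRNAs in non-ischemic samples 1 to 4 and by 94, 106 and 91 in ischemic samples 1 to 3, while 103 miRNAs gave no product in any sample. The tested set was 103 miRNAs with a Ct below 35 in at least 3 samples, and 76 were below it in all 7.

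In the ischemic wound edge the erythroid miRNA miR-451 and the muscle miRNAs miR-1 and miR-133a had higher mean levels, and miR-324-5p, the epithelial miRNA miR-200b, the neural miRNA miR-124a and miR-31, a miRNA of migrating keratinocytes, had lower ones. miR-451 was 8.08-fold higher (log2 difference 3.01 ± 0.68 SE), with 2.33 without ischemic sample 1, 3.71 without ischemic sample 3 and 1.77 with late Ct set to 35. miR-324-5p, known to act on Hedgehog signalling, was 5.09-fold lower (-2.35 ± 0.52), with a Ct above 35 in all 3 ischemic samples. With late Ct set to 35 it was at -0.64 (adjusted p = 0.519 in limma). miR-31 was 4.86-fold lower (-2.28 ± 0.71), but 2.57-fold lower (-1.36 ± 0.43, adjusted p = 0.102 in limma) without ischemic sample 3. miR-200b, which holds cells in an epithelial state, was 3.94-fold lower (-1.98 ± 0.50), and miR-124a 3.16-fold lower (-1.66 ± 0.46). In each of these 5 miRNAs the ischemic and non-ischemic samples did not overlap. None passed an adjusted p of 0.05 in limma against 5S rRNA with all 7 samples. There miR-451 and miR-324-5p had an adjusted p of 0.0872, miR-200b of 0.120, miR-124a of 0.156 and miR-31 of 0.189. miR-451 did pass after global median and after quantile normalization.

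**Figure D1:**
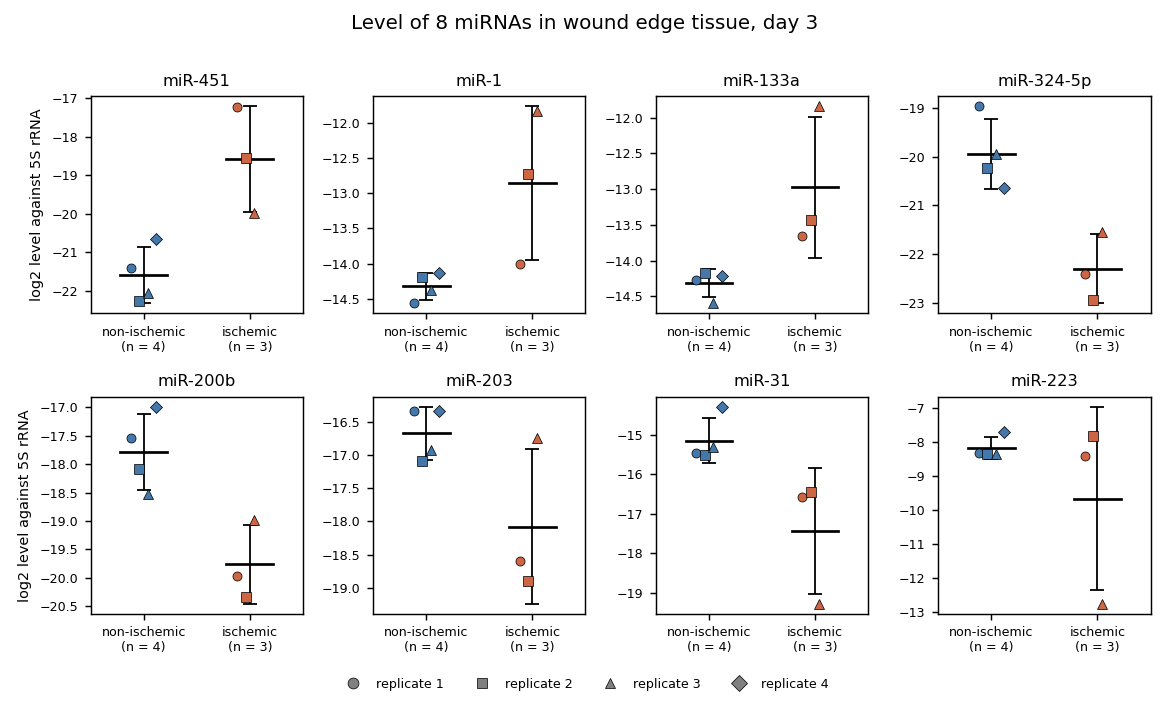
Log2 level against 5S rRNA (vertical axes, each with its own range) of 8 miRNAs in the non-ischemic (n = 4) and ischemic (n = 3) samples, where symbols mark replicate numbers, horizontal lines the group mean and bars the SD. Ischemic and non-ischemic samples do not overlap for miR-451, miR-1, miR-133a, miR-324-5p, miR-200b and miR-31, and ischemic sample 3 lies at -12.76 for miR-223, a deviation of -4.58 from the non-ischemic mean.

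Over all 103 miRNAs, limma against 5S rRNA called 0 at an adjusted p of 0.05 (smallest 0.0872), while 19 had an unadjusted p under 0.05, against 5.15 expected by chance. Of these 19, 5 were higher and 14 lower in ischemic samples, a balance that depended on the normalization. Over samples left out in turn the count of 19 ran from 10 to 21. The groups did not overlap for 18 miRNAs (17.5%), where chance gives 5.71%. An unmoderated two-sample test per assay called 1 miRNA after adjustment, miR-218 (adjusted p = 0.0341 in that test and 0.219 in limma). Its log2 difference was -0.91 ± 0.32, where the SE is that of limma. The SD of miR-218 between samples was 0.12 in the non-ischemic and 0.16 in the ischemic group. The remaining miRNAs among the 12 with the smallest p were miR-699 (-1.12), miR-1 (1.46), miR-214 (-1.53), miR-133a (1.34), miR-376a (-1.22) and miR-378 (1.27), with adjusted p of 0.189 for miR-699 and 0.219 for the others in limma. The median difference of the tested miRNAs was -0.35, so that 79 had a lower and 24 a higher mean in ischemic samples. The share with a lower mean was 76.7% against 5S rRNA, 82.5% against snoRNA (68.0% without snoRNA202, which has a far value in non-ischemic sample 2) and 67.0% on raw Ct, but 56.3% against 5S rRNA without ischemic sample 3. Global mean, global median and quantile normalization, which centre each sample and so hold the share near its middle, gave 51.5%, 49.5% and 47.6%. Directions are therefore given against 5S rRNA, with the value relative to this shift for several of the lists. Relative to the shift, miR-451 was 3.37 higher and miR-324-5p, miR-31 and miR-200b were 1.99, 1.93 and 1.62 log2 units lower.

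Ischemic sample 3 stood apart from the rest. Its correlation across the 76 miRNAs detected in all samples with the other 6 samples was 0.756 to 0.830, where miRNAs are not independent replicates, against 0.963 to 0.977 among non-ischemic samples, 0.964 between ischemic samples 1 and 2, and 0.908 to 0.942 between these and the non-ischemic samples. The myeloid miRNA miR-223, which had the highest mean level on the plate over all 7 samples, deviated by -4.58 log2 units (24.0-fold lower) from the non-ischemic mean there. The leukocyte miRNAs miR-142-3p and miR-142-5p deviated by -4.32 and -4.17 (Ct values of 35.05 and 36.6), miR-18a, which stands on the leukocyte list and also belongs to the miR-17-92 clusters, by -5.23 (Ct of 39.6), miR-31 by -4.12 and the wound-induced miR-21 by -2.53. Its muscle miRNAs lay at the other end, with miR-1 and miR-133a at 2.48 each and miR-133b at 2.23 above the non-ischemic mean. In ischemic samples 1 and 2, the mean of the 4 leukocyte miRNAs was 0.14 and 0.16, within the range of -0.51 to 0.76 of the non-ischemic samples, whereas it was -4.58 in ischemic sample 3.

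Without ischemic sample 3, a comparison of 2 with 4 samples, 8 miRNAs passed an adjusted p of 0.05 in limma. miR-451 rose by 3.71 ± 0.55 (SE, log2, adjusted p = 0.00877). The other 7 fell: miR-324-5p with a difference of -2.73 ± 0.49 (adjusted p = 0.0146), miR-200b of -2.37 ± 0.47 (0.0176) and miR-203, a miRNA of differentiating keratinocytes, of -2.08 ± 0.39 (0.0146), with miR-124a at -2.004 and miR-127 at -2.01 (both 0.0188). miR-484 at -2.03 (0.0188) and miR-149 at -1.9997 (0.0476) lie outside the rule for named miRNAs and were chosen after their values were seen. In ischemic sample 3 itself, 6 of the 8 deviated in the same direction, 3 of them (miR-451, miR-324-5p and miR-124a) by more than 2 SD of the non-ischemic samples, while miR-203 deviated by -0.08, miR-484 by -0.10, miR-127 by 0.23 and miR-149 by 1.57. The median deviation of all tested miRNAs in that sample was -0.53, so a lower level there lends the 7 lower calls little weight. With all 7 samples the differences were -1.41 ± 0.56 for miR-203 (adjusted p = 0.219), -1.39 ± 0.58 for miR-484 (0.219), -1.26 ± 0.62 for miR-127 (0.351) and -0.81 ± 0.89 for miR-149 (0.734) in limma. With no filter on late Ct and without ischemic sample 3, 1 miRNA passed and it was none of the 8.

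Muscle miRNAs had higher means in the ischemic wound edge. All 4 tested members of the skeletal and cardiac muscle list had a higher mean, by 1.09 log2 units on average and 1.45 relative to the median of all miRNAs, with miR-1 at 1.46 ± 0.51 (SE), miR-133a at 1.34 ± 0.48, miR-133b at 1.23 ± 0.47 and miR-206, which is typical of regenerating muscle, at 0.34 ± 0.48. These are miRNAs of muscle fibres, and miR-1, miR-133a and miR-133b were among the 10 miRNAs with the lowest mean Ct over all 7 samples. The list was the only one of 15 to pass camera (adjusted p = 0.000221), but the adjusted p was 0.685 with an estimated correlation and 0.317 in fry. No member passed over all miRNAs in limma, and 3 passed when adjusted over the list alone. The list mean per sample was 0.21, 1.11 and 1.96 above the non-ischemic mean in ischemic samples 1 to 3. Non-ischemic samples ran from -0.20 to 0.26, so that ischemic sample 1 lay within their range. The highest value stood in ischemic sample 3, the sample with low leukocyte miRNAs. Without that sample the mean was 0.66, with miR-1 at 0.95, miR-133a at 0.77 and miR-133b at 0.72, and the camera adjusted p was 0.127.

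Keratinocyte miRNAs had lower means in 5 of 5 tested members, -0.86 on average and -0.50 relative to the median of all miRNAs, and the list did not pass camera (adjusted p = 0.615). After global mean and global median normalization 4 and 3 of the 5 were lower. miR-200b and miR-203 had the largest differences, and miR-429 (-0.49 ± 0.55 SE), which is encoded beside miR-200b, and miR-200c (-0.35 ± 0.39) differed by less than their error. The remaining member, miR-205, chosen after its values were seen, showed no fall, at -0.05 ± 0.60. It lay 0.30 above the median of all miRNAs, and was at 0.07 without ischemic sample 3. miR-200c turned to 0.01 under global median normalization. The list mean was -1.03 and -1.17 in ischemic samples 1 and 2 and -0.37 in ischemic sample 3, against -0.61 to 0.63 in non-ischemic samples. When adjusted over the list alone, 1 member passed with all 7 samples, and 2 without ischemic sample 3.

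Both erythroid miRNAs on the plate had higher means in ischemic samples. miR-451 was the only miRNA detected in all samples of a group and in no sample of the other, in 3 of 3 ischemic and 0 of 4 non-ischemic samples (Fisher's exact test p = 0.0286, the smallest these sizes allow, before adjustment for 306 miRNAs). Its mean Ct was 33.1 in ischemic and 36.2 in non-ischemic samples, so the lower level lies beyond the detection limit. miR-486 was 2.18 ± 1.02 (SE) higher with an adjusted p of 0.321 in limma, and its non-ischemic samples spread with an SD of 1.94. Its groups overlapped, with ischemic samples 1 to 3 at 1.57, 1.41 and 3.55 from the non-ischemic mean and non-ischemic sample 1 at 1.95. It was highest in ischemic sample 3, where miR-451 was lowest of the ischemic samples, at 1.61. The difference of miR-486 was 1.46 without non-ischemic sample 3, 1.49 without ischemic sample 3 and 2.83 without non-ischemic sample 1.

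Leukocyte, inflammation, wound and lymphocyte miRNAs had lower means, which in the first 3 lists depended on ischemic sample 3. The 4 myeloid and pan-leukocyte miRNAs had a list mean of -1.43, or -1.07 relative to the median of all miRNAs, and of 0.15 without that sample. The 4 inflammation-induced miRNAs had a list mean of -0.62 (-0.27 relative to that median), and of -0.13 without ischemic sample 3, with miR-146b at -0.90 ± 0.37 (SE) and miR-146a, which restrains NF-kB signalling, at -0.78 ± 0.37. These 2 stayed at -0.79 and -0.62 without ischemic sample 3, while miR-155 (-0.35 ± 0.57) and miR-21 (-0.46 ± 0.77) turned to 0.34 and 0.57. miR-155 also turned to 0.13 under quantile and to 0.00 under global median normalization. The 6 wound-induced miRNAs, led by miR-31, had a list mean of -0.94 (-0.59 relative to the median), and of -0.14 without ischemic sample 3, where 2 of 6 were lower. The 3 lymphocyte miRNAs, led by miR-342 (-0.98 ± 0.51), had a list mean of -0.47, or -0.11 relative to the median, with 2 of 3 higher after global mean normalization. Their list mean was -0.58 without ischemic sample 3 and lowest in ischemic sample 1, at -0.85. None of these 4 lists passed camera, with adjusted p of 0.615 for the first 3 and 0.859 for lymphocytes, and 0 members passed when adjusted over each list alone.

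**Figure D2:**
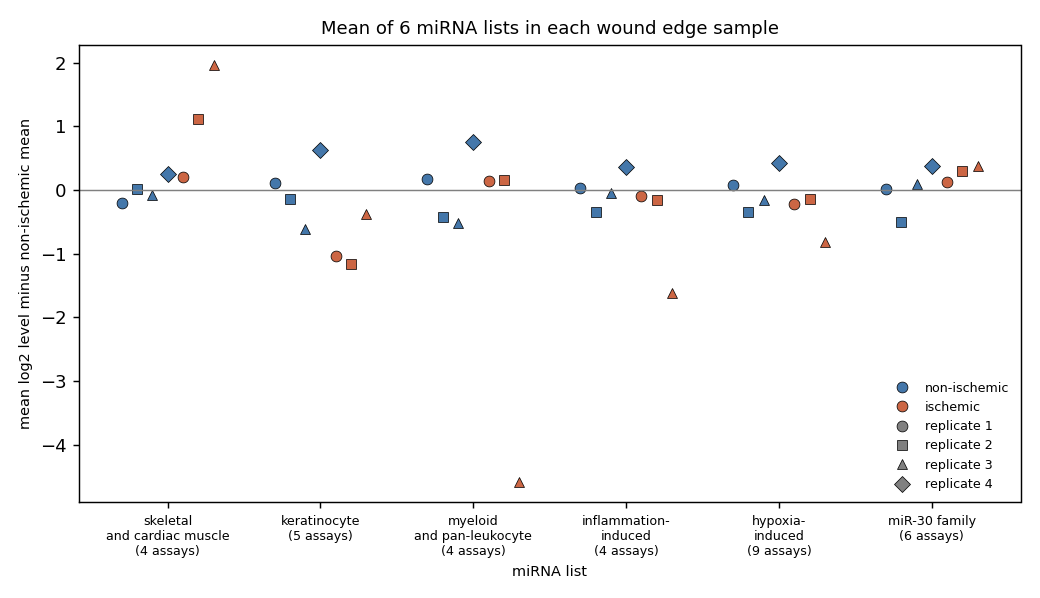
Mean log2 level of 6 miRNA lists in each sample, minus the non-ischemic mean (vertical axis), for the lists named on the horizontal axis, where colours mark groups and symbols replicate numbers. The leukocyte list of ischemic sample 3 lies at -4.58 and its muscle list at 1.96, whereas the keratinocyte list is lowest in ischemic samples 1 and 2, at -1.03 and -1.17.

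The hypoxia and vessel lists did not pass camera. The 9 tested hypoxia-induced miRNAs had means lower by -0.39 on average, which is -0.04 relative to the median of all miRNAs, with miR-26b at -0.79 ± 0.42 (SE) and miR-103 at -0.60 ± 0.40, and after global mean normalization 5 of 9 were lower and 4 higher. Their camera adjusted p was 0.859. Of the pro-angiogenic miRNAs, 1 of 4 was higher, miR-378, and 3 were lower (list mean -0.48, adjusted p = 0.930), with the endothelial miRNA miR-126 at -0.46 ± 0.37. The anti-angiogenic list, which shares miR-200b and miR-214, had 9 of 10 lower (-0.64, or -0.29 relative to the median of all miRNAs, adjusted p = 0.615), with 5 of 10 after global mean normalization. miR-497 was at -1.30 ± 0.76 through ischemic sample 1, without which it was at -0.27, against -2.01 without ischemic sample 3. In the pro-angiogenic and the anti-angiogenic list 1 member each, miR-31 and miR-200b, passed when adjusted over the list alone in limma, and in the hypoxia-induced list 0.

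miR-210, the miRNA most widely used as a marker of hypoxia, was near or beyond the detection limit in all samples. Its Ct was 34.4 and 33.8 in ischemic samples 1 and 2, 40 in ischemic sample 3, and 37.5, 37.8, 40 and 37.4 in non-ischemic samples 1 to 4. The log2 difference was 1.97 and did not exceed the spread between samples (exact permutation p = 0.286, n = 4 and 3). Since only 2 samples had a Ct below 35, miR-210 was not among the miRNAs tested with limma. Over samples left out in turn the difference ran from 0.86, without ischemic sample 2, to 3.92, without ischemic sample 3. The latter had an exact permutation p of 0.0667, the smallest that 15 splits allow.

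The other lists held no call. The miR-30 family was higher in 6 of 6 members by 0.26 on average, with miR-30d at 0.66 ± 0.42 (SE) and miR-30a-5p at 0.31 ± 0.34. The 6 include the passenger form miR-30a-3p, chosen after its values were seen, at 0.06 ± 0.41. The family had a camera adjusted p of 0.0971. It passed with the preset correlation after global mean normalization, where the mean was 0.60, but not with an estimated correlation, neither there (smallest adjusted p of any list 0.567) nor against 5S rRNA (0.973). After snoRNA normalization 3 of 6 members were higher, but 6 of 6 when snoRNA202 was left out of the reference, and 3 of 6 were higher against 5S rRNA without ischemic sample 3. The let-7 family was lower in 4 of 4 members by -0.54 (adjusted p = 0.615), led by let-7b (-0.98 ± 0.40) and let-7c (-0.70 ± 0.40), with 3 of 4 lower after global mean and 2 of 4 after quantile normalization. The imprinted Dlk1-Dio3 cluster had 5 tested members of 37 on the plate, of which 4 were lower and miR-434-3p higher (0.52 ± 0.40), for a list mean of -0.68 (adjusted p = 0.763); miR-337 was at -0.85 ± 0.50. The miR-17-92 clusters were lower in 9 of 10 members, with miR-17-5p at -0.97 ± 0.57, in 5 of 10 after global mean normalization and in 3 of 10 without ischemic sample 3 (adjusted p = 0.930 with all samples). The fibroblast list had 2 of 3 members lower (adjusted p = 0.859), and the family of miR-99, miR-100 and miR-125 2 of 3 (0.930), the latter 1 of 3 after global mean normalization. Adjusted over each of these lists alone, 0 members passed with all 7 samples, while 1 passed in the Dlk1-Dio3 cluster and 1 in the family of miR-99, miR-100 and miR-125 without ischemic sample 3. Both tested neural miRNAs were lower, and of the lists too small to test, smooth muscle had 1 member at -0.04 and the miR-29 family 2 with a mean of -0.35, which was -0.02 after global mean normalization. No melanocyte, liver or embryonic miR-290 member had a Ct below 35 in any sample.

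Reference and control RNAs did not differ between groups in exact permutation tests (n = 4 and 3). The Ct of 5S rRNA was 14.6 ± 0.15 (SD) in non-ischemic and 14.5 ± 0.062 in ischemic samples (exact p = 0.257), and that of 18S was 12.1 ± 0.31 and 11.8 ± 0.35 (exact p = 0.343). Mean Ct values of snoRNA142 and snoRNA251, read with SYBR, differed by -0.13 and -0.19 cycles (exact p = 0.457 and 0.343), that of snoRNA202 by -1.03 (0.600), that of snoRNA135 by -1.36 (0.857) and that of snoRNA234 by 0.24 (0.543, all exact permutation tests). snoRNA202 and snoRNA135 had Ct values of 31.96 and 39.5 in non-ischemic sample 2, above those of the other 6 samples. The assays of snoRNA142 and snoRNA251 not marked SYBR gave a Ct of 40 in every sample, and so were not part of the snoRNA reference. The number of miRNAs with a Ct below 35 was 98.8 ± 4.03 (SD) in non-ischemic and 97.0 ± 7.94 in ischemic samples (exact p = 0.800). The median log2 level of the 76 miRNAs detected in all samples was -16.40 ± 0.40 and -16.76 ± 0.22 (exact p = 0.229).

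In the authors' deposited table, 19 miRNAs had a fold of at least 2 upward and 28 downward. Of these, 12 and 16 had a Ct below 35 in fewer than 3 samples, and 10 and 12 never had one. Of the 20 most extreme folds in the authors' deposited table, 12 belonged to such miRNAs with fewer than 3 detections. For miR-210 the authors' deposited table gives a fold of 8.31, a ratio of arithmetic means, where the geometric means give 3.92. By geometric means 13 of the 19 and 23 of the 28 stay at 2-fold or more. The 103 miRNAs without product in any sample all carry a fold of 0.916 in the authors' deposited table, since for these only the 5S rRNA Ct differed.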

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

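The tests of explanations for the 3 patterns were chosen after the values were seen, whereas the counts over other splits of the samples were planned. Of 68 reported quantities examined in the 4 non-ischemic samples, 3 had a sample far from the others, where chance gives about 3.40. miR-223 was highest in non-ischemic sample 4, at a log2 level of -7.70 against -8.33 in the next sample. miR-30d was lowest in non-ischemic sample 2, at -19.49 against -18.43. snoRNA202 had a Ct of 31.96 in non-ischemic sample 2 against 28.29 in the next.

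Leukocyte miRNAs were low in ischemic sample 3, at a list mean of -4.58. Less RNA or poorer amplification there, alike for all miRNAs, is argued against. The median of all tested miRNAs deviated by -0.53 in this sample, and the 4 leukocyte miRNAs lay at -4.05 log2 units from that median. miR-223 alone, at a Ct of 27.3, deviated by -4.58. This test was chosen after the gap was seen, and a loss particular to some assays was not tested. Whether a non-ischemic sample is out of place was not decided over the 103 tested miRNAs. The lowest correlation between non-ischemic samples, 0.9319, hardly exceeded the highest of ischemic samples 1 and 2 with them, 0.9317. Over the miRNAs detected in all samples these were 0.963 and 0.942. An exchange of ischemic sample 3 with a non-ischemic sample of this series is nevertheless argued against as the source. Over the 103 tested miRNAs ischemic sample 3 correlated at 0.728 to 0.857 with any other sample, against 0.932 to 0.971 among non-ischemic samples. A lower share of leukocytes in that piece of tissue could be a source but stays open: the span between the 4 members was 1.06, yet miR-142-3p, miR-142-5p and miR-18a had Ct values of 35.05, 36.6 and 39.6 there, past the detection limit, so the span decides nothing. The lymphocyte list of the same sample was at -0.25, with miR-342 at -1.28, so that a loss of all leukocytes alike is not shown, and miR-18a also belongs to the miR-17-92 clusters. A sample from outside the series, skin taken away from the wound, or a wound with little infiltration would look alike and stay open, and no biological explanation other than that share was tested.

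Muscle miRNAs had higher means in ischemic samples. A group difference in 5S rRNA is argued against as the cause, since the mean difference of the list was 0.94 with snoRNA in its place and 1.19 without snoRNA202 among these, against 1.09. More muscle in the ischemic samples, such as from the layer beneath the skin, could raise all members by about the same amount, but miR-206 differed less than miR-1. A span between members as large as the observed 1.12 came up in 5 of the 35 splits of the samples (highest other 1.37), too often to exclude that source and too seldom to favour it. Ischemia itself is untested among the open explanations. For the count of lists past camera, chance cannot be excluded: the real grouping gave 1, and 20 of the 35 splits gave at least as many, the highest other giving 4.

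Keratinocyte miRNAs had lower means in ischemic samples, but the list did not pass camera (adjusted p = 0.615), so whether there is a difference to explain is itself open. Fewer keratinocytes in the samples could be a source. The members differed by unequal amounts, with a span of 1.93, and 4 of the 35 splits gave a span as large (highest other 2.18), so the samples are too few to decide, and an effect of ischemia on single miRNAs remains untested.

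For miRNAs past an adjusted p of 0.05 with all 7 samples in limma, the real grouping gave 0 and the highest of the others 1. A count of 0 is matched by 35 of 35 splits whatever the data, so this comparison says nothing about chance. For the 19 miRNAs at an unadjusted p under 0.05, 1 of the 35 splits, the real one, gave as many and the highest other gave 13. That share is the smallest that 35 splits allow, and the samples may not be independent. Chance is therefore made less likely for this count but is not excluded. Without ischemic sample 3, the real grouping gave 8 miRNAs past the adjusted p and the highest other gave 1 (1 of 15 splits gave as many), and 15 splits are too few for a share under 0.05.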

How the results depend on the processing

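Settings that combine the loss of ischemic sample 3 with another choice, and snoRNA normalization without snoRNA202, were added after the data were seen, and all others were planned. The cause of a change was not tested unless one is given. The 0 miRNAs called by limma with all 7 samples became 1 under global median and under quantile normalization (miR-451 in both) and 1 in the unmoderated two-sample test per assay (miR-218), and stayed 0 under the other settings that kept all samples. Over samples left out in turn the count ran from 0 to 8, and only the loss of ischemic sample 3 gave calls. Without it, snoRNA and global mean normalization gave 7 each, all among the 8, and no filter on late Ct gave 1, miR-503, chosen after its values were seen, with every Ct above 35. The 19 miRNAs at an unadjusted p under 0.05 became 12 of the 53 with a Ct below 32 in at least 3 samples, and 10, 11 and 12 without non-ischemic samples 1, 3 and 4. Of the 19, 14 were lower, whereas 7 of 15, 6 of 14 and 8 of 17 were lower under global mean, global median and quantile normalization.

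The count of lists past camera was 1 with all samples and 2 under global mean, global median, raw Ct, no filter and linear values, each time adding the miR-30 family. It ran from 0 to 1 over samples left out, with 0 without ischemic sample 3, 0 when snoRNA or global mean normalization was added to that, and 1 without a filter. With an estimated correlation it was 0 in every setting run. The direction of miR-210 and of the overall level held in every setting that gave a value, none past the threshold. Global mean, global median and quantile normalization fix the overall level, and the filters, treatments of late Ct and variance models leave it as it is, so these gave no separate value. Nor could quantile normalization or late Ct set to missing be run for miR-210, or late Ct set to missing and the unmoderated test for lists.

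Several miRNAs turned direction, and no turned value passed the threshold. miR-200c was at 0.00648 under global median normalization and miR-155 at 0.00479, with 0.13 under quantile normalization. With late Ct set to missing, which removes ischemic sample 3, miR-142-5p was at 0.43 and miR-142-3p at 0.46. On linear values miR-21 was at 0.00305 and miR-149 at 0.22. Over samples left out in turn, the ranges were -2.40 to 0.0656 for miR-223, -1.89 to 0.43 for miR-142-5p, -1.99 to 0.46 for miR-142-3p, -0.76 to 0.34 for miR-155 and -1.08 to 0.57 for miR-21, with -2.22 to 0.15 for the leukocyte list, each upper end without ischemic sample 3. For miR-149 the range was -1.9997, past the threshold without ischemic sample 3, to 0.23 without ischemic sample 1. Other changes over 1.5-fold without one sample were those of miR-18a, at -0.35 without ischemic sample 3, miR-214, at -2.19 without ischemic sample 2, and miR-17-5p and miR-484, at -1.67 and -0.76 without ischemic sample 1, besides those given with the results. With late Ct set to 35, miR-324-5p was at -0.64, miR-451 at 1.77, miR-376a at -0.53, miR-486 at 0.79 and miR-18a at -0.57. With late Ct set to missing, miR-486 was at 0.55, miR-18a at -0.76 and miR-497 at -0.27. On linear values miR-223 was at -0.49, miR-142-3p and miR-142-5p at -0.29 each and miR-18a at -1.08, and under quantile normalization miR-18a was at -0.77 and miR-486 at 2.77. Without snoRNA202 in the snoRNA reference, 0 miRNAs and 1 list were called and the overall level was at -0.26. Without ischemic sample 3 and with snoRNA normalization, miR-223 was at 0.0795, miR-142-5p at 0.44, miR-142-3p at 0.48, miR-155 at 0.35, miR-21 at 0.59 and the leukocyte list at 0.16. With global mean normalization these were 0.33, 0.69, 0.73, 0.61, 0.84 and 0.42, and miR-200c 0.00144. Without a filter they were 0.0656, 0.43, 0.46, 0.34, 0.57 and 0.15. The difference in detected miRNAs ran from -6.25 to 1.25, the latter without ischemic sample 3. miRNAs detected in 1 group only numbered 0 at a Ct below 32, 1 at a Ct below 38 (miR-299-5p in place of miR-451) and 1 to 3 over samples left out: miR-324-5p was added without non-ischemic sample 4, miR-376a and miR-692 without ischemic sample 2, and miR-210 without ischemic sample 3. The Ct difference of snoRNA135 ran from -2.05 to 0.28 and that of snoRNA234 from -0.0114 to 0.57.

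Whether the replicate numbers pair the samples is not known. Deviations of same-numbered samples from their group means correlated at -0.08, -0.30 and -0.11. These 3 values show no pairing but cannot exclude it, since the ischemic mean includes the distant ischemic sample 3. With the replicate number as a block over the 3 pairs, 0 miRNAs and 1 list were called, and 7 miRNAs had an unadjusted p under 0.05, with fewer samples in that fit; miR-210 was at 2.29 and the overall level at -0.20. Late Ct limits what can be said of miR-451 in non-ischemic samples, of miR-324-5p in ischemic samples, and of miR-142-3p, miR-142-5p and miR-18a in ischemic sample 3.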

Other observations

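The miRNAs named in this paragraph were chosen after their values were seen, from their mean level over all 7 samples. miR-223 had the highest level of all miRNAs on the plate, with a Ct of 22.8 ± 0.21 (SD, n = 4) in non-ischemic samples, as is known of tissue rich in neutrophils. It was followed by miR-709, with 23.8 ± 0.24 in the same samples, and miR-720, an annotation now known to be a fragment of a transfer RNA, with 26.0 ± 0.48. miR-24, miR-26a, miR-16 and miR-191, which most tissues express, were also among the first 10. The muscle miRNAs miR-133b, miR-1 and miR-133a were among these 10 as well, and in non-ischemic wounds had Ct values of 28.6 ± 0.33, 29.0 ± 0.23 and 29.0 ± 0.24 (SD, n = 4), so they were detected in both groups. These orders set assays of unlike efficiency side by side and are descriptive only.

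Ischemic sample 3 held 12 miRNAs more than 2 log2 units below the non-ischemic mean. Beyond the leukocyte list, which shares miR-18a with this group, they included miR-19a (-3.33), miR-106a (-2.60) and miR-17-5p (-2.003) of the miR-17-92 and related clusters, known to be active in dividing cells, whose list mean there was -1.93 against 0.23 and 0.15 in ischemic samples 1 and 2. miR-19a and miR-106a were chosen after their values were seen.

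A hypothesis written before its result was seen was that miRNAs whose genes are neighbours move together from sample to sample, as parts of 1 transcript could. Within groups, 30 pairs with genes within 10 kb had a median correlation of 0.61 across the 7 samples, against 0.20 for 3881 other pairs. Of 10000 random sets of 30 other pairs, 10 reached that median, and the 95th percentile was 0.44. Without ischemic sample 3, a check added afterwards, the values were 0.61 for neighbours, 0.41 for other pairs and 0.57 for the 95th percentile. The test is therefore consistent with co-transcription, but pairs such as miR-19a with miR-19b or let-7b with let-7c have nearly the same sequence, so that primers may read both, which was not tested, and pairs share members.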
